A study of Mus musculus with 4 samples.

How the data were processed

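RNA from Mac1-positive bone marrow cells was hybridised in 1 colour (Cy3) to 4 Agilent whole mouse genome arrays, 2 for wild-type and 2 for miR-223 knockout mice. The deposited scanner files hold intensity values that, per the file headers, were made with Agilent Feature Extraction 10.5.1.1: the processed signal is background-subtracted and detrended within the array, with surrogate values for dim spots, and was not normalized between arrays. Surrogate values made up 18.2% to 22.7% of the gene spots, no gene spot was saturated, and repeated spots of a probe varied by a median CV of 5.01% to 6.38%. The deposited value table is on a log2 scale. Compared with the scanner values it equals log2 of the processed signal plus 1 constant per array, which sets the 4 array medians to 5.56, and all single-spot probes matched within 0.01. No header or label states how that constant was chosen.

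Groups and replicate numbers were taken from the sample titles. Control spots were left out, spots of 1 probe were averaged, log2 processed signal was taken and the array's 75th percentile subtracted. Of 41174 probes, 147 with an outlier flag on any spot of any array were left out, and so were probes that were not well above background on both arrays of at least 1 group. The flags removed the probes of Il1b, Stat3, Tgfb1 and Myd88, which were well above background, so an alternative that left out flagged spots one by one was added after the data were seen. For a gene with several probes the probe with the highest mean over the 4 arrays was used, and probes without a gene symbol were tested on their own, which left 17681 features, 13826 of them with a symbol. Probes of 2681 of the 5912 genes with several tested probes had fold changes of opposite sign. Names came from the RefSeq table (assembly GRCm38.p6), which matched 26690 probes by accession, 5189 by symbol and 952 by synonym, and 8343 kept the name in the file. Probe positions are those of the array files, on mm9, and the RefSeq table was used only for names and for which genes neighbour each other, with none of its coordinates.

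KO was compared with WT by limma 3.58.1 (lmFit and eBayes, in R 4.3.3) with Benjamini-Hochberg adjustment and a threshold of 0.05. The 25 gene lists and the tests were fixed before the data were examined. The lists cover genes described as miR-223 targets, primary granules, secondary granules, mature neutrophils, monocytes, macrophages, cell cycle, type I interferon, interferon gamma, cytokines and chemokines, arginine metabolism with alternative activation, oxidase, lysosome, pattern receptors, cholesterol synthesis, immediate early genes, progenitors, B cells, T and natural killer cells, erythroid cells, megakaryocytes, eosinophils, basophils and mast cells, dendritic cells, and stroma with endothelium. Each list was tested by camera with a preset correlation of 0.01, and beside it by camera with an estimated correlation and by fry, which tests whether a list's genes move on balance one way. Both of these rest on the 2 residual degrees of freedom of 4 arrays. By fry 0 lists passed after adjustment over the lists (adjusted p = 0.0779 for the target list, the lowest), though 1 or 2 passed under some alternatives. A transcript well above background in 1 group only was given as a bound: the mean of the bright group against the dim group's mean, in which each array's value was the higher of the probe's own signal and the lowest signal among probes well above background.

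Named genes followed a rule fixed before the data were examined. It took up to 12 genes per direction that passed the test and were well above background on all 4 arrays. Their WT and KO arrays also had to be free of overlap, and places left were filled by smallest p. It also took up to 5 per direction with a bound, and up to 4 members of each list past the test or otherwise the 2 with the smallest p. A fixed set was added (Mef2c, Igf1r, Nlrp3, E2f1, Il6, Cxcl2, Ccl3, Nos2, Arg1 and the genes of the sex check). Ctsz, Cbx5, Gspt1 and genes around Gspt2 were named after their values were seen. One member that the rule takes from a list is not reported here.

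The steps were tested on simulated data with the means of the 17681 features, the fitted spread and 200 changed features. Of features changed 1.5-fold 0% were called, of those changed 2-fold 16%, of those changed 4-fold 84% and of those changed 8-fold 98%, with 8 unchanged features called. In 20 simulations without any change at most 1 feature was called, and in 1 simulation a list passed camera. The settings of the simulation name no correlation between genes, so its list result is no guide to lists of correlated genes. The alternatives were normexp background correction (offset 50), quantile normalization, median scaling, no filter on dim probes, a filter requiring all 4 arrays, an intensity trend, the replicate number as a block, the deposited value table, every probe on its own, an estimated correlation, and leaving out each array in turn, in which the lone array of a group is assumed to vary like the other group. A planned test of genes with miR-223 seed sites was not run because no 3′ untranslated sequence was used here. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.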

Results

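Messenger RNA was measured in cells carrying Mac1 (the integrin CD11b, found on neutrophils, monocytes, macrophages, eosinophils and natural killer cells) that had been sorted from the bone marrow of male BALB/c mice 4 weeks after a footpad infection with the parasite Leishmania major. Wild-type mice (WT) were compared with mice lacking the microRNA miR-223 (KO), with 2 one-colour arrays per group. On the 4 arrays, 64.1% to 66.8% of the gene spots lay well above background, and the number of arrays limits the precision of every value. The labels do not say whether an array held RNA of 1 mouse or of several, so p-values measure only the spread between these samples. Within a group the arrays correlated at 0.995 (WT) and 0.994 (KO) across the features tested, and between groups at 0.989 to 0.993. Both WT arrays shared 1 slide and scan and both KO arrays another, so slide and genotype cannot be told apart in any comparison below.

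The array carried no probe named for miR-223, so the deletion itself was not checked. The label of male mice was met by the Y-linked genes Ddx3y, Eif2s3y and Kdm5d, which were well above background on all 4 arrays, while 4 Xist probes were above it on no array. The difference of Ddx3y between groups was 0.08 ± 0.13 (log2 ± SE, n = 2 per group), and 1 of its 2 probes went the other way. For Eif2s3y the difference was -0.06, for Kdm5d 0.11 and for Uty -0.41, none past the test.

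The first comparison asked which transcripts differed in Mac1-positive marrow cells without miR-223. Among transcripts measured well above background on all 4 arrays, KO cells had 6.58-fold less Gtsf1, a protein of the piRNA pathway of germ cells, 6.30-fold less of the aspartic protease gene Asprv1, and 5.44-fold less Kcnj8, the pore subunit of an ATP-sensitive potassium channel. Entpd3, an enzyme that hydrolyses extracellular nucleotides, was 5.12-fold lower and Gspt2, a translation termination factor, 4.92-fold lower. Perp, a membrane protein induced by p53, fell by 1.74 ± 0.13 and Ggt1, which cleaves extracellular glutathione, fell by 1.72 ± 0.14 (log2 ± SE, n = 2 per group). Mcam, the adhesion molecule CD146, rose 3.11-fold and Il1r1, the signalling receptor for interleukin-1, rose 2.84-fold. Adjusted p of these 9 genes (limma, Benjamini-Hochberg) lay between 0.0128 for Gspt2 and Kcnj8 and 0.0325 for Il1r1. Only genes whose WT and KO arrays did not overlap could be named here, so their lack of overlap adds no support. All 9 also passed with normexp background correction, which adds an offset to every spot. All 9 log2 differences were then smaller: -2.55 for Asprv1, -1.70 for Gtsf1, -1.61 for Gspt2, -1.29 for Perp, -1.22 for Kcnj8, -0.94 for Entpd3, -0.87 for Ggt1, 1.18 for Mcam and 0.74 for Il1r1. Another such feature, a probe that names no gene, fell by 1.65 on the log2 scale.

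**Figure D1:**
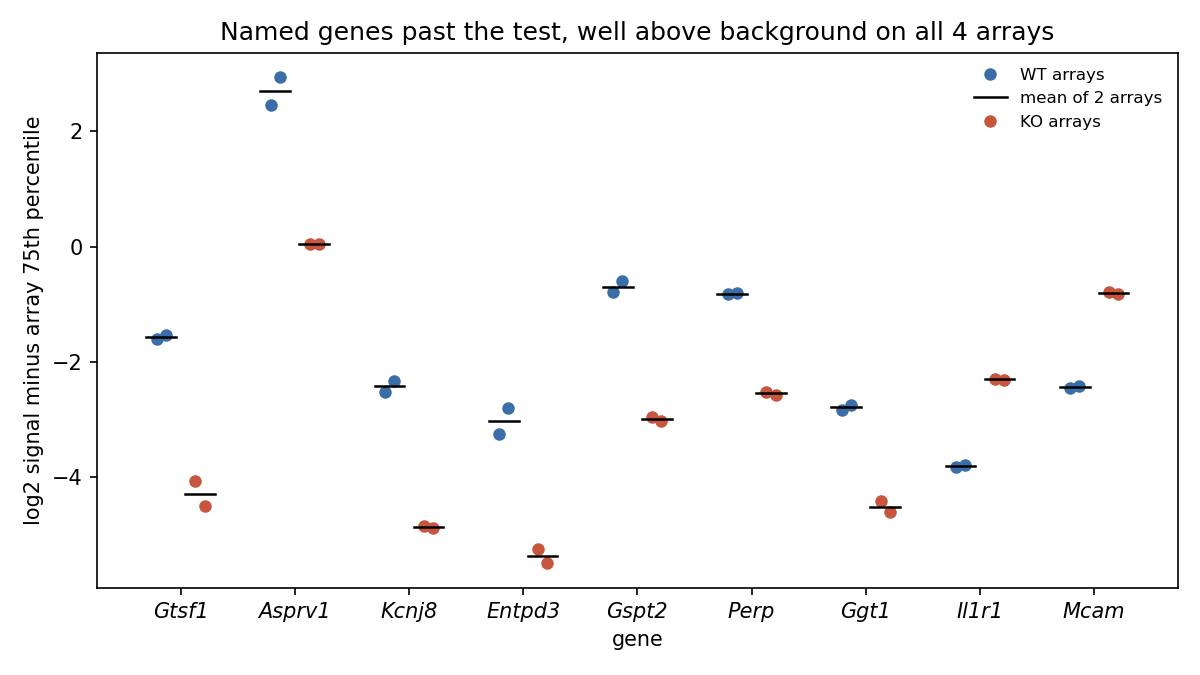
Signal of the 9 named genes that passed the test and were well above background on all 4 arrays. The vertical axis is log2 signal minus the array's 75th percentile, each point is 1 array (blue WT, red KO) and each bar the mean of 2 arrays. The WT arrays of Gspt2 lie at -0.79 and -0.60 and the KO arrays at -2.96 and -3.02.

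The Gspt2 probe lay on chromosome X at 91883426 to 91883485 (mm9, as the array files give it). The probe of Kcnj8 lay on chromosome 6 at 142514004 to 142514063 and that of Asprv1 on the same chromosome at 86579351 to 86579410. Gtsf1 was read at chromosome 15, 103232937 to 103235246, by a probe whose 2 ends span that stretch, and its other probe gave -2.83. Mcam was read at chromosome 9, 43950521 to 43950580, and its other probe gave a smaller rise of 1.18. Il1r1 was read at chromosome 1, 40372667 to 40372726. Whether these probes lie in coding sequence or a 3′ untranslated region is not given in the sources used here.

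Some transcripts passed the test but were well above background in 1 group only, so that only a bound can be given. Mapk15, an atypical MAP kinase, was at least 3.74-fold higher in KO cells (adjusted p = 0.0128, limma). Dach2, a transcription cofactor, was at least 1.25-fold higher, but with normexp background correction its difference was -0.02 (adjusted p = 0.957). In the other direction, Crip3 was at least 3.81-fold lower in KO cells, the odorant receptor gene Olfr923 at least 2.94-fold, the acute phase gene Orm3 at least 2.75-fold, the neurotensin receptor gene Ntsr2 at least 2.26-fold and H2bl1 at least 2.04-fold. With normexp background correction the differences of these genes were smaller than the bounds. The offset of 50 shrinks the differences of dim probes, so these smaller values do not test the bounds. The bounds are given for the main processing only. Mapk15 stood at 0.58 (adjusted p = 0.0575, limma), Ntsr2 at -0.43 (adjusted p = 0.138) and H2bl1 at -0.48 (adjusted p = 0.105), none past the test. Crip3 at -0.57, Olfr923 at -0.74 and Orm3 at -0.59 passed.

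Of 17681 features tested, 7 were higher and 20 lower in KO cells at an adjusted p under 0.05, and 17 of these 27 were not well above background on all 4 arrays. With each array's median as the scaling point the counts were 20 higher and 32 lower, and with quantile normalization 7 and 12. Median scaling put the median log2 fold change of all features at 0.05, against -0.05 with the 75th percentile. The counts moved widely with the array left out. In such a fit 1 group holds a single array, so a changed count cannot tell dependence on that array from a weaker test. The named genes that passed the test and were well above background on all 4 arrays kept their direction whichever array was left out. Only genes without overlap of WT and KO arrays could be named, so this was fixed in advance and adds no support. The groups did not overlap in 45.9% of all features, against 33.3% expected by chance with 2 arrays per group.

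Genes that came next by p did not pass and are given as values. Among the higher ones were Ly6a, the progenitor antigen Sca-1, at 1.33 ± 0.15 (log2 ± SE, n = 2 per group, adjusted p = 0.0635, limma), Tal2 at 1.32, C1qtnf6 at 1.32, the heparan sulfate proteoglycan gene Sdc2 at 1.28, Mgl2, a lectin of macrophages and dendritic cells, at 1.19, Pla2r1 at 1.18, Basp1 at 1.16, Btbd11 at 1.16, B630019K06Rik at 1.14 and the lysosomal membrane protein gene Tmem106b at 1.08. Among the lower ones were Thbs4 at -1.93, Olfr930 at -1.70, Sema7a, a semaphorin, at -1.48, Cdkl2 at -1.32 and Penk, the precursor of enkephalins, at -1.19. Their adjusted p lay between 0.052 and 0.0809.

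The second comparison asked whether genes described in the literature as direct targets of miR-223 were higher without it. Of 38 measured targets, 29 lay above the median of all features and 9 below, and the list's median lay 0.15 above it on the log2 scale. The list passed camera, which sets a list against all other genes with a preset correlation (adjusted p = 2.28e-04 over 25 lists), but not with a correlation estimated from the arrays (adjusted p = 0.647). No target passed over all genes tested, against 6 higher with normexp and 2 with an intensity trend, and 4 were higher when adjusted over the list alone, all 4 named here: Lmo2, a transcriptional regulator of blood formation, at 0.88 ± 0.16, the cathepsin genes Ctsl at 0.77 ± 0.14 and Ctsz at 0.61, and Cbx5, a heterochromatin protein, at 0.66 (log2, ± SE, n = 2 per group). That count by limma was 0 without WT replicate 1 (5 at an unadjusted p under 0.05), WT replicate 2 (9), KO replicate 2 (8) or a filter on dim probes (6), 2 without KO replicate 1, and 7 with normexp or an intensity trend. The list's median was 0.26 without KO replicate 1 and 0.23 without a filter. Igf1r, the receptor for insulin-like growth factor 1, stood at 0.66 ± 0.16 (adjusted p = 0.201, limma), with its 4 probes between 0.04 and 0.73. Other targets stood close to 0: Mef2c at 0.04, Nlrp3 at 0.06 and E2f1 at 0.06, while the chemokine genes Cxcl2 and Ccl3 stood at 0.49 and 0.38 and the cytokine gene Il6 at -0.22, none past the test. In the target list, 10 members also stood in another list, and without them the median of the other 28 lay 0.14 above that of all features (adjusted p = 0.00391 by camera, adjusted p = 0.903 with an estimated correlation), a list chosen after the data were seen. Of these 28 targets, 0 were higher by limma when adjusted over that list alone.

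**Figure D2:**
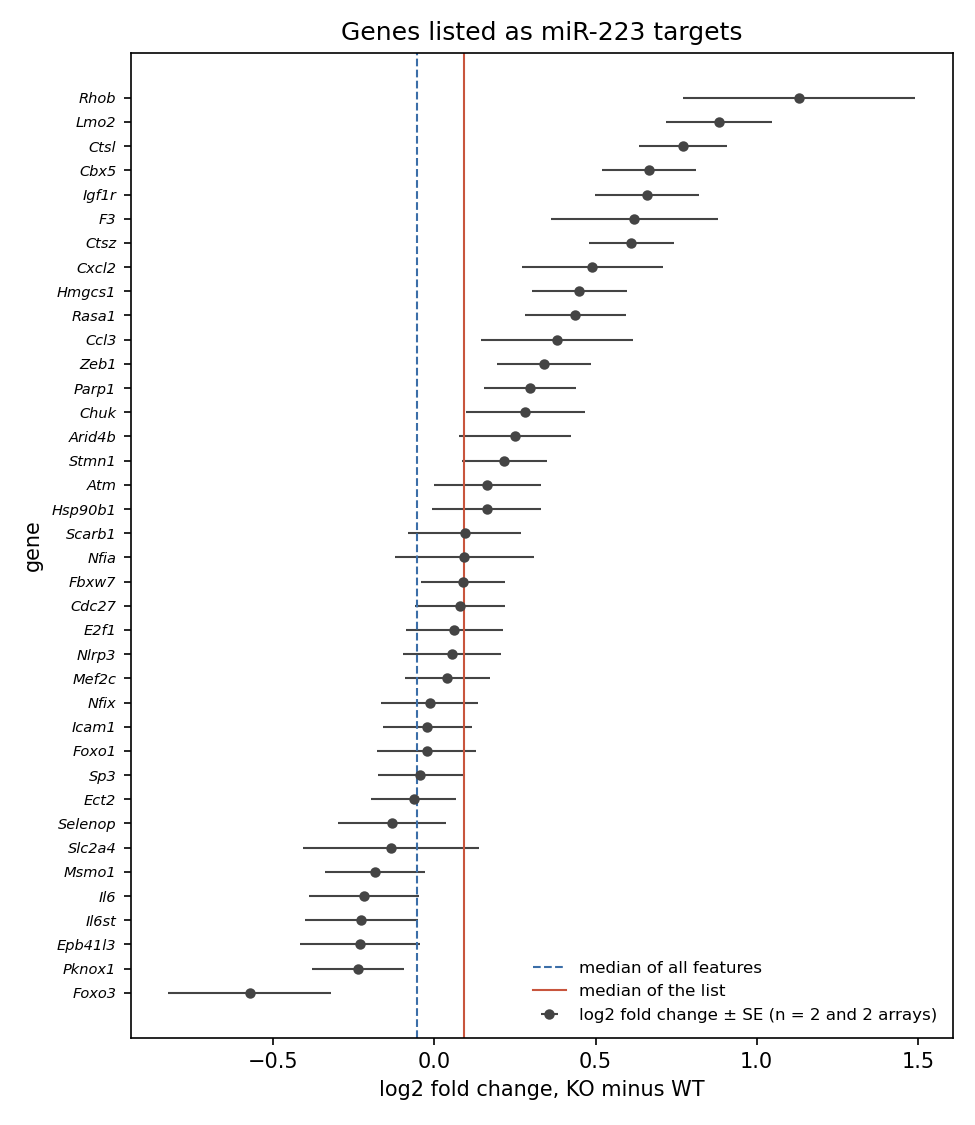
Log2 fold change (KO minus WT, horizontal axis) of the 38 measured genes listed as miR-223 targets, 1 gene per line, with bars of 1 SE from 2 arrays per group. The red line is the list's median at 0.09 and the dashed line the median of all features at -0.05, and 29 of the genes lie above the latter.

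The primary granule genes, made by early neutrophil precursors, stood higher in KO cells: 9 of 9 lay above the median of all features, with a list median 0.37 above it (camera adjusted p = 6.00e-06, adjusted p = 0.647 with an estimated correlation). Prtn3, which encodes proteinase 3, stood at 0.93 ± 0.14 and the cystatin gene Cst7 at 0.77 ± 0.14 (log2 ± SE, n = 2 per group), and 4 members passed when adjusted over the list alone. Without WT replicate 2 that count by limma was 0, with 4 at an unadjusted p under 0.05. Of 17 secondary granule genes, 8 lay above and 9 below the median of all features (camera adjusted p = 0.993), with Padi4 at -0.61 and the NADPH oxidase gene Cybb at 0.50. Of 20 genes of mature neutrophils, 9 lay above and 11 below (camera adjusted p = 0.777), and Stfa1 and Stfa2, both cysteine protease inhibitors, stood at -1.31 and -0.91 and passed when adjusted over the list alone. Of mature neutrophil genes 0 were lower by that test (limma) without WT replicate 1 (2 at an unadjusted p under 0.05), WT replicate 2 (3) or a filter on dim probes (2), and 1 without KO replicate 2.

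Lists of basophils and mast cells, eosinophils, macrophages, monocytes and interferon response were lower in KO cells by camera. Of 10 basophil and mast cell markers 9 lay below the median of all features, with a list median of -0.47 relative to it (camera adjusted p = 5.91e-04, adjusted p = 0.903 with an estimated correlation), and 6 were lower when adjusted over the list alone. That count was 2 without WT replicate 1 and 4 without KO replicate 2, with quantile normalization or with median scaling, and the list's median was -0.31 with normexp. Under normexp, median scaling, the value table, the filter requiring all 4 arrays, an intensity trend or the replicate block, 1 marker was higher when adjusted over the list alone. The basophil proteases Mcpt8 and Prss34 stood at -1.26 ± 0.20 and -1.11 ± 0.17 (log2 ± SE, n = 2 per group). Of 9 eosinophil markers 8 lay below, with a list median of -0.28 (camera adjusted p = 0.00249, adjusted p = 0.978 with an estimated correlation) and 4 lower when adjusted over the list alone, among them Alox15 at -1.004 and the eotaxin receptor gene Ccr3 at -0.51. The 4 fell to 0 by limma without WT replicate 1 (2 at an unadjusted p under 0.05), WT replicate 2 (2), KO replicate 1 (3) or a filter on dim probes (4) and with median scaling (3). They fell to 1 without KO replicate 2 or with the deposited value table and to 2 with quantile normalization. Of 17 macrophage genes 16 lay below, with a list median of -0.27 (camera adjusted p = 0.00249, adjusted p = 0.978 with an estimated correlation), with the sialoadhesin gene Siglec1 at -0.62 and the complement gene C1qc at -0.51. Of 20 monocyte genes 16 lay below, with a list median of -0.29 (camera adjusted p = 0.00883, adjusted p = 0.996 with an estimated correlation), with the Fc receptor gene Fcgr1 at -1.04 and Klf4 at -0.62. Of 26 genes induced by type I interferon 24 lay below, with a list median of -0.18 (camera adjusted p = 0.00116, adjusted p = 0.978 with an estimated correlation), with Rtp4 at -0.63 and Ifit1 at -0.53, and no member of the last 3 lists passed when adjusted over the list alone. With normexp 5 macrophage, 10 monocyte and 8 interferon genes were lower by that test, and with an intensity trend 2, 5 and 6. With the filter requiring all 4 arrays 5 monocyte genes were lower by it. Under normexp, an intensity trend, this filter or the replicate block, 1 monocyte gene was higher by that test. Without KO replicate 1 there were 2 macrophage genes lower by it, and without KO replicate 2 there were 1 monocyte and 5 interferon genes. The monocyte, type I interferon and eosinophil lists no longer passed camera without KO replicate 1 (medians of -0.13, -0.12 and -0.28), and the monocyte list did not pass without WT replicate 2 (-0.15) or without a filter on dim probes (-0.20). The macrophage median was -0.39 without KO replicate 1 and -0.11 without KO replicate 2. Without KO replicate 2 the type I interferon median was -0.42 and the monocyte median -0.43, and without WT replicate 1 the eosinophil median was -0.16. The interferon median was -0.11 with normexp and -0.091 without a filter.

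**Figure D3:**
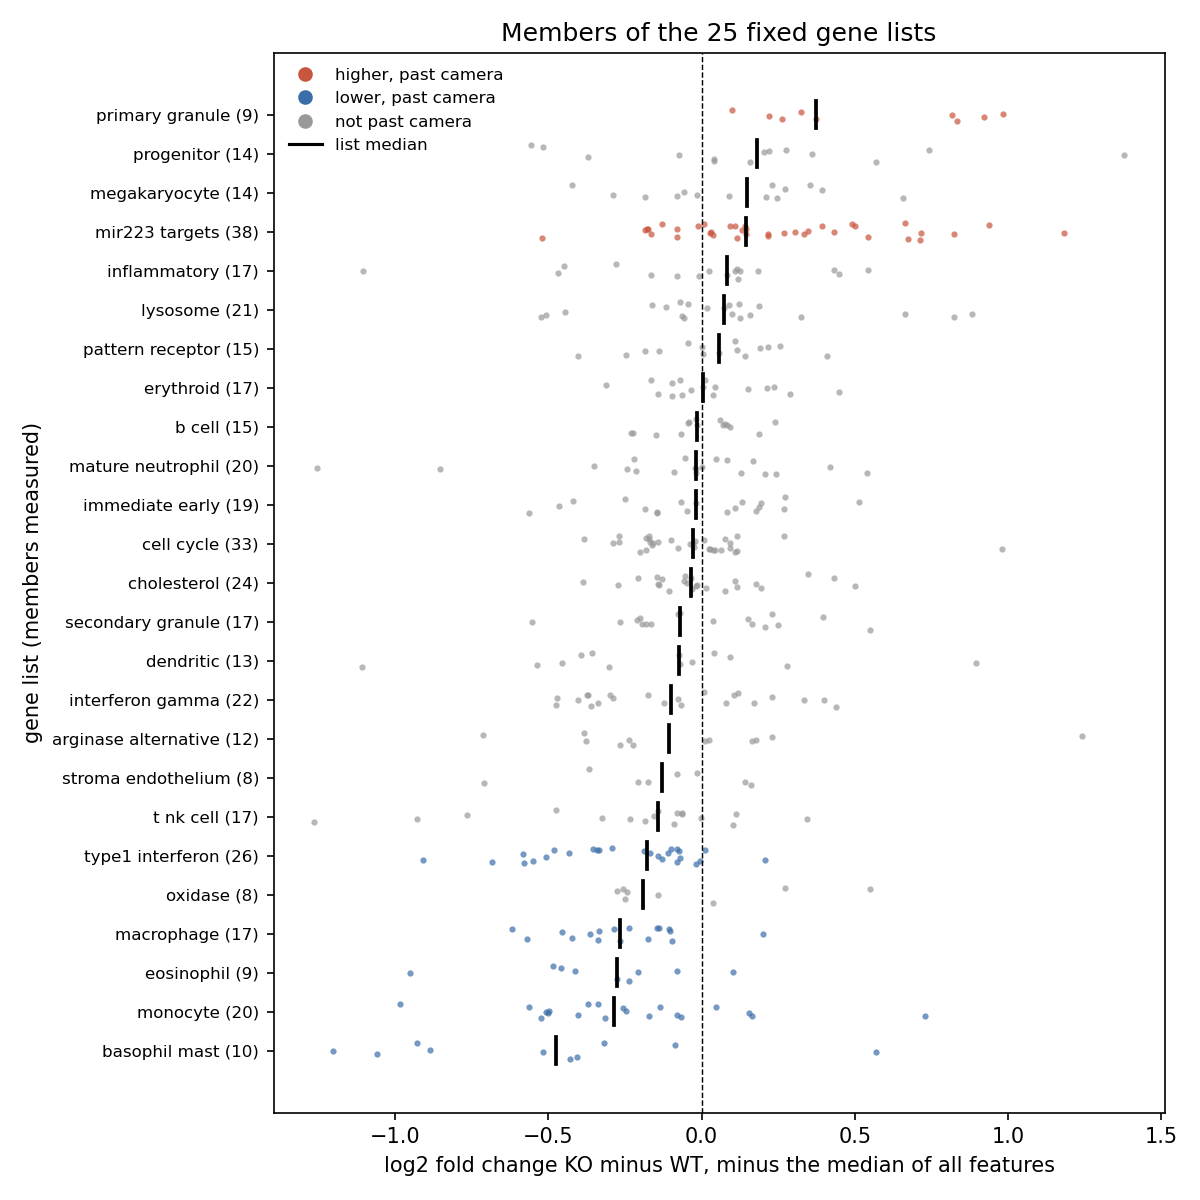
Members of the 25 gene lists, each point 1 gene, as log2 fold change (KO minus WT) minus the median of all features (horizontal axis), with black bars at list medians and the number of measured members beside each name. Red and blue points belong to the 2 lists higher and the 5 lists lower by camera, from primary granule genes at 0.37 to basophil and mast cell markers at -0.47.

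The other lists did not pass camera, and their medians are given relative to the median of all features. Progenitor genes stood at 0.18 (camera adjusted p = 0.0526) with 2 members, Ly6a and Hlf (0.69), higher when adjusted over the list alone. Markers of T and natural killer cells stood at -0.14 (camera adjusted p = 0.0526). Of these, Cd3d at -1.32 and Cd3g at -0.98, both parts of the T cell receptor complex, were lower when adjusted over the list alone. Their mean WT signals lay far apart, at 5.07 for Cd3d and -4.19 for Cd3g (log2, relative to the array's scaling point). Their probes lay close together on chromosome 9, and whether the falls of Cd3d and Cd3g reflect T cells was not tested. Among markers of other cells, the median was -0.01 for B cells (Pax5 at -0.28, Igll1 at -0.20), 0.15 for megakaryocytes (Itgb3 at 0.61, with 1 of its 2 probes going the other way, and Clec1b at -0.48), -0.07 for dendritic cells (Siglech at -1.16 and Cd209a at 0.84, both past when adjusted over the list alone) and -0.13 for stroma and endothelium (Col1a2 at -0.42, Pecam1 at -0.23), with camera adjusted p between 0.418 and 0.993. Erythroid markers stood at 0.00401 with both arrays of each group and differed between the arrays of both groups, with the higher level in replicate 1 of each. The list was lower without WT replicate 2 (-0.37, camera adjusted p = 0.00715) and higher without WT replicate 1 (0.30, camera adjusted p = 1.68e-04). Its median was -0.19 without KO replicate 1 (camera adjusted p = 0.659) and 0.21 without KO replicate 2 (camera adjusted p = 0.077). The transcription factor gene Klf1 stood at -0.36 and Rhag at 0.40.

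Cytokine and chemokine genes had a median of 0.08, and Ccl2, a chemokine for monocytes, stood at -1.16 ± 0.15 (log2 ± SE, n = 2 per group) and was lower when adjusted over the list alone, with Csf1 at -0.52. For arginine metabolism and alternative activation the median was -0.11, with Mgl2 higher and Ccl24 (-0.77) lower when adjusted over the list alone. Arg1, which encodes arginase 1, was well above background on no array, nor was Nos2, which encodes the inducible nitric oxide synthase. Interferon gamma genes stood at -0.10 (Psmb9 at -0.46, Psmb8 at -0.42) and oxidase and antimicrobial genes at -0.19 (Cybb at 0.50, Ncf4 at -0.30). Lysosomal genes stood at 0.07, where Ctsl and Ctsz were among the members higher when adjusted over the list alone. Pattern receptor genes stood at 0.06 (Pycard at -0.46, Nod2 at -0.30), cholesterol genes at -0.03 (Hmgcs1 at 0.45 with 1 of its 3 probes opposed, Hsd17b7 at -0.44), immediate early genes at -0.02 (Nr4a1 at -0.47, Ier2 at -0.24 with 1 of 2 probes opposed) and cell cycle genes at -0.03 (Rrm2 at 0.93, higher when adjusted over the list alone, and Hmgb2 at -0.44). Camera adjusted p of these 9 lists lay between 0.407 and 0.993. Some of the lists that did not pass camera did so without 1 array. These were progenitor genes without WT replicate 1 (0.31) or KO replicate 2 (0.20), though without WT replicate 2 their median was 0.017, T and natural killer cell markers without WT replicate 2 (-0.23), dendritic cell markers without WT replicate 2 (-0.46), megakaryocyte markers without WT replicate 1 (0.23), lysosomal genes without WT replicate 2 (0.16) and interferon gamma genes without KO replicate 2 (-0.30). With normexp the progenitor (0.14), T and natural killer cell (-0.11) and lysosomal (0.11) lists passed. The progenitor and the T and natural killer cell lists also passed under other settings, among them a filter requiring all 4 arrays (0.18 and -0.14). Counts adjusted over the list alone moved too. Of T and natural killer cell markers 4 were lower with normexp, an intensity trend or the replicate number as a block. With the filter requiring all 4 arrays 3 were lower, and 1 with quantile normalization or without a filter on dim probes. By limma, 0 lysosomal genes were higher by that test without WT replicate 1, WT replicate 2 or KO replicate 1 (3 at an unadjusted p under 0.05 in each), and 0 cell cycle genes were higher without any 1 of the 4 arrays (1 at an unadjusted p under 0.05 in each). Of progenitor genes 1 was higher without WT replicate 1 or KO replicate 2, and of T and natural killer cell markers 1 was lower without KO replicate 2. Of the genes of arginine metabolism and alternative activation 0 were lower by limma without WT replicate 2 (2 at an unadjusted p under 0.05) or KO replicate 1 (3), and of dendritic cell markers 0 were higher without WT replicate 1 (1). For the secondary granule, cholesterol and immediate early lists camera's direction was up with a median below that of all features, and for the cytokine list it was down with a median above it. Over all 25 lists, 0 of 413 measured members passed over all genes tested by limma, and 81 had an unadjusted p under 0.05. With normexp 17 members were higher and 16 lower over all genes tested, with an intensity trend 8 and 6, and 2 and 6 without KO replicate 1. There was 1 higher and 0 lower with median scaling, as with the deposited values.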

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

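The tests with flagged spots left out one by one and of the target list without shared members were chosen after the data were seen. In every alternative that kept all 4 arrays and camera's preset correlation, except every probe on its own, which gave counts only (10 higher and 23 lower), the 9 named genes well above background on all 4 arrays kept their direction, and the miR-223 target, primary granule, macrophage, type I interferon, eosinophil and basophil and mast cell lists passed camera. Camera was run without the intensity trend, so that alternative could not change its result for a list. Median scaling and the deposited value table both set the array medians equal, so for the lists they count as 1 alternative. The counts of genes moved more, as higher and lower in KO: 116 and 169 with normexp (13 of the 27 shared), 7 and 12 with quantile normalization (18 shared), 20 and 32 with median scaling and with the deposited value table (27 shared in each), 2 and 7 when all 4 arrays had to be above background (9 shared), and 51 and 69 with an intensity trend (22 shared). Without a filter on dim probes limma called 0 and 0 of 27974 features, with 2051 at an unadjusted p under 0.05. The cause of these moves was not tested. Leaving out 1 array gave 1 to 38 higher and 0 to 142 lower, and 4 to 10 lists past camera, the fewest without KO replicate 1. With an estimated correlation 0 lists passed, a test on 2 residual degrees of freedom. By fry the primary granule list passed with median scaling (adjusted p = 0.00364), the value table (0.0057) and the replicate block (0.0341), and the target list without a filter on dim probes (0.0168) and with the replicate block (0.0341). With the replicate number as a block the counts were 46 and 111 (27 shared), 2 list members were higher and 5 lower over all genes tested, and 7 monocyte and 7 type I interferon genes were lower and 7 targets higher when adjusted over the list alone. Deviations of same-numbered arrays correlated at 0.22 over only 2 pairs, too few to show whether the numbers pair the samples.

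The following directions turned, all but that of Dach2 for results not past the test. With normexp, Dach2 stood at -0.019, E2f1 at -0.00185, Nlrp3 at -0.082, and list medians at 0.064 (mature neutrophil), 0.017 (cell cycle), 0.00999 (cholesterol), 0.046 (immediate early) and 0.089 (B cell). With quantile normalization they were 0.073 (secondary granule), 0.044 (mature neutrophil), 0.019 (immediate early) and 0.042 (B cell). Without a filter they were 0.017 (secondary granule), 0.069 (mature neutrophil), 0.060 (cell cycle), 0.053 (cholesterol), 0.054 (immediate early) and 0.073 (B cell). The B cell list stood at 0.023 with flagged spots left out one by one. Eif2s3y stood at 0.051 with median scaling and 0.050 with the value table. Over the 4 arrays left out in turn, list medians ran from -0.029 to 0.12 (cytokine), -0.056 to 0.16 (lysosome), -0.043 to 0.13 (pattern receptor), -0.0051 to 0.053 (immediate early), -0.15 to 0.14 (B cell), -0.23 to 0.049 (T and natural killer cell), -0.46 to 0.096 (dendritic), -0.11 to 0.087 (secondary granule), -0.059 to 0.068 (mature neutrophil), -0.37 to 0.30 (erythroid), -0.30 to 0.12 (interferon gamma) and -0.052 to 0.26 (megakaryocyte). Genes ran from -0.76 to 0.032 (Klf1), -0.046 to 0.17 (E2f1), -0.18 to 0.073 (Eif2s3y), -0.15 to 0.37 (Kdm5d) and -0.077 to 0.19 (Nlrp3). Signal over background limits the dim calls: 12 of the 27 were above background on no KO array and 5 on no WT array. The seed site test and its alternatives were not run for want of 3′ untranslated sequence, and slide as a block was not run because no slide held both groups.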

Other observations

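The tests of cell shares (with their comparison markers and left-out arrays), of the stretch of chromosome X, of the slide and of other groupings of the arrays were chosen after the results they bear on were seen, as were the genes named in the next paragraph.

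Several immune genes left out for an outlier flag were read once only their flagged spots were dropped, and none of those named here passed limma's test. Il1b, which encodes the inflammatory cytokine interleukin-1 beta, had a log2 fold change of -0.16 ± 0.22 (SE, n = 2 per group), and Il18, of the same cytokine family, -0.43 ± 0.13. The miR-223 target Stat3, a transcription factor of cytokine signalling, stood at 0.21 ± 0.25, Myd88, the adaptor of Toll-like receptors, at -0.16 ± 0.15 and Tgfb1 at -0.03 ± 0.17.

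The target list stood 0.15 above the median of all features on the log2 scale. A drift of fold change with signal is argued against, since the list's median lay at the 99.96th percentile of 10000 lists matched on mean signal. A single array is argued against too, since the list's median stayed at least 0.11 above that of all features whichever array was left out. An effect of slide or scan stays open and cannot be told apart from genotype, since 0 slides held both groups. An extreme place among matched lists was not particular to targets. Primary granule genes lay at the 100th percentile, lysosomal genes at 99.26 and progenitor genes at 98.92, while monocyte, macrophage and type I interferon genes lay at 0. Loss of repression by miR-223 may account for the shift of the targets as a hypothesis, for which no seed site test was run.

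Basophil, mast cell and eosinophil markers (19 genes) had a median log2 fold change of -0.47, against -0.05 for 46 markers of B cells, erythroid cells and megakaryocytes. These lists were picked as low, so genes were permuted over 10 cell type lists with the pick of 2 lists repeated in each of 10000 permutations, and genes are not independent replicates. The difference from the 121 markers of the 8 other lists was -0.32 (one-sided permutation p = 0.0040), the lowest of any 2 lists. It was -0.22 without WT replicate 2, -0.36 without WT replicate 1, -0.32 without KO replicate 1 and -0.34 without KO replicate 2. In each of these fits another 2 lists stood lower, at -0.26, -0.47, -0.36 and -0.39 in the same order. A lower share of every cell type other than the main one therefore stays open. A drift with signal is argued against, since the median lay at the 0th percentile of 10000 lists matched on mean signal. The pick of 2 lists was not repeated for that percentile. Matched lists also leave out the correlation within a list, estimated at 0.14 for basophils and mast cells and 0.26 for eosinophils. Fewer basophils and eosinophils in KO marrow, a lower level per cell and an effect of slide are candidate explanations that stay open.

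Gspt2 lies on chromosome X, with 9 protein-coding genes between it and Mir223, which the RefSeq table places between Msn and Vsig4. Its fall of 2.30 on the log2 scale was not part of a shift of the whole stretch: the other 30 genes with a probe within 5 Mb of the midpoint of the Msn and Vsig4 probes had a median change of 0.16 in size, at the 51.4th percentile of runs of as many neighbouring genes (24 genes and the 51.6th percentile when centred on Gspt2), and 0 of them passed limma's test, with 5 at an unadjusted p under 0.05 (16.7%, against 12.5% of all features), Zxda at 0.56, Pdk3 at 0.53, Maged1 at -0.40, Vsig4 at -0.84 and Gdpd2 at least 1.43-fold higher (well above background on 0 WT arrays). Signal shared with the paralog Gspt1 is argued against, since Gspt1 stood at 0.28 (95% interval -0.17 to 0.73) by its brightest probe, and its other 2 probes at -0.08 and -0.22 had intervals reaching down to -0.51 and -0.78, all above the fall of Gspt2. A sequence difference under the single Gspt2 probe, or a regulatory change that came with the deleted allele, may account for the fall, and neither was tested. A shift of a stretch was tested on chromosome X only. On chromosome 9 the probes of Olfr923, Olfr930, Mcam, Cd3g and Cd3d lay between 38636160 and 44794402 (mm9), with Mcam higher and the others lower. Those of Ly6a, Mapk15 and C1qtnf6 on chromosome 15, all higher, lay between 74825553 and 78354182, with Ncf4 at -0.30 in the same stretch. These genes were picked after their values were seen, and neither stretch was tested. Of the 3 splits of the 4 arrays into pairs, the real one called 27 features and the highest other 0, too few splits for a share under 0.05.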
